A study of Homo sapiens with 40 samples.

How the data were processed

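Gastrocnemius muscle biopsies were profiled by RNA sequencing in 4 groups of 10 libraries. Control libraries came from people without peripheral artery disease, and IC libraries from patients with intermittent claudication, the exertional leg pain of that disease. IC-post libraries came from the patients of the IC group, sampled again 6 months after revascularization, per the series' design text, and CLI libraries from patients with critical limb ischemia, its most severe form. Per the labels' protocols, total RNA was isolated with a commercial kit, and libraries were made with a total RNA kit of the kind that depletes ribosomal RNA. Such libraries hold unspliced and non-polyadenylated RNA beside mature messenger RNA, and what depletion leaves of ribosomal and other structured RNA takes a share of the values. The genome build was hg38, per the submitters' processing notes. The aligner, the counter and the annotation release are not given in the sources used here.

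The deposited table holds TPM (reads divided by gene length and scaled to the same total in each library) for 45394 Ensembl gene identifiers in 40 libraries. That the deposited values are TPM was inferred from the table itself: each library sums to 1000000, and the smallest value above 0 differs between genes of a library. No scaling between libraries was applied by the authors as far as the values show. TPM has a consequence for every fold change below, because a class of RNA that takes a larger share of a library lowers all other genes of that library. Of the identifiers, 45262 matched a table of gene symbols. Gene coordinates, biotypes and lengths came from GENCODE release 29 on the same build, which listed 43204 of them. No 2 libraries held identical values, and the highest correlation between 2 libraries was 0.981 across genes on the log2 scale.

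Depth was estimated, since TPM keeps no totals. Libraries were put on a common step through genes seen in few of them, and the lowest value of a gene was then taken as a single read. For 6105 genes seen in 8 to 25 libraries, this value times the exon length lay within 1% of a common constant in 88.0%. The estimates run from 0.85 M to 30.59 M reads per library (M, 1000000). Of values estimated under 20 reads, 74.6% were within 0.1 of a whole read, so that whole counts were not recovered. Depth sets how well low genes were measured, and CLI libraries were the shallowest. The mean TPM of 381 olfactory receptor genes, which muscle does not use, served as a measure of background.

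Genes with a mean of at least 10 TPM over the 40 libraries were tested, 6883 in each comparison, leaving out XIST, TSIX and genes of the Y chromosome. Values were analysed as log2(TPM + 1), so that fold changes of low genes are understated. The main test was limma (version 3.58.1 in R 4.3.3, beside Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9) with a mean-variance trend, fitted to the libraries of the 2 groups compared, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Every adjusted p in the text comes from it unless another test is named. The words rose, fell and changed are kept for genes or lists past the threshold. Errors of fold changes are moderated standard errors, and levels are means ± SD over 10 libraries. Counts of libraries above or below a group mean use log2 values. The 5 comparisons were IC, CLI and IC-post against Control, CLI against IC, and IC-post against IC.

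Gene lists covering metabolism, contraction, innervation, hypoxia, vessels, matrix, stress, inflammation and cell types were written down beforehand, 40 in all. A list was tested with at least 5 tested members, which held for 32 lists, by limma's camera with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison. Camera asks whether a list moved differently from the other genes tested. It was repeated with a correlation estimated from the data, and fry was run beside it, which asks whether the members moved on balance at all. Counts of members past the threshold are given over all genes and adjusted over the list alone. The other 8 lists reached 5 members only with a filter of 1 TPM. Some lists share members, so their results are not independent. The hypoxia-induced list shares genes with the glycolysis and angiogenic lists, and the matrix list with the fibroblast list.

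Named genes follow a rule: per comparison, the 10 protein-coding genes with the largest rise and the 10 with the largest fall among those past the threshold with a mean of at least 50 TPM, up to 4 members of smallest p from each list, and, where fewer than 5 passed in a direction, the 5 of smallest p given as values. The text names fewer than the rule takes, and a few results are not reported here. Genes with near-identical copies or pseudogenes (SAA1, EEF1A1, FTH1, HBA2, MT2A, HSP90AA1 and the sarcomeric myosins) are uncertain, because reads could be split between copies in a way the sources used here do not give. Overlapping mitochondrial genes (MT-ATP6 with MT-ATP8, MT-ND4L with MT-ND4) are uncertain in the same way.

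Alternatives were other pseudocounts, filters and scalings, one fit over all libraries, array weights, robust variance estimates, the replicate number as a block, covariates, leaving out each library in turn, and limma's voom on the estimated reads. One scaling, TMM (the trimmed mean of log ratios between libraries, trimming 30% of ratios and 5% of intensities at each end), centres the bulk of genes. It is given beside the deposited scale for counts of changed genes, for lists where it ends or makes a call of camera, and for the members that passed in CLI against Control. IC and IC-post libraries were treated as pairs by replicate number, since both groups are the same 10 patients; the labels do not state that the numbers mark patients. Deviations from the group means of same-numbered IC and IC-post libraries correlated across genes with a median of 0.33 (lowest 0.04, highest 0.62), 9 of 10 were over 0.1, and 8 correlated best with their own number, against a median of -0.04 for other numbers. They were taken on the deposited scale, where the share of mitochondrial ribosomal RNA moves most genes of a library. That share went with the number in CLI as well, so these correlations cannot tell the same patient from shared processing. The main design has no block, and the blocked value is given where it changes a call.

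The scripts were tested on simulated normal data with the spread of each gene in the real libraries, 200 changed genes among the 6883 and a list lowered by 0.6 log2. Camera called that list in all 5 simulations and none of the other 31. Genes were drawn independently of each other, so this cannot show how often camera calls lists whose genes move together. Splits of the real libraries, given below, called many lists. At a log2 change of 1, limma recovered 77 of 100 genes in a simulation of IC against Control, 77 in CLI against Control, 61 in CLI against IC, 77 in IC-post against IC and 91 in IC-post against Control. At a log2 change of 2, it recovered 96, 95, 100, 99 and 97. Wrong calls numbered 10, 9, 9, 6 and 9 in the same order, again among genes drawn independently. Simulated TMM factors were recovered within 0.021 log2. The replicates are separate people within a group, and characteristics of these people were not used here.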

Results

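RNA of the gastrocnemius, the calf muscle whose exertional pain defines claudication, was measured in 40 libraries. There were 10 libraries each of Control, IC (intermittent claudication, before revascularization), IC-post (the same 10 patients 6 months after it) and CLI (critical limb ischemia). Estimated depth was 17.0 ± 9.48 M reads in Control (SD, n = 10; 4.84 to 30.59), 16.8 ± 5.86 in IC (10.05 to 30.22), 12.4 ± 5.49 in IC-post (3.35 to 20.31) and 8.12 ± 4.97 in CLI (0.85 to 17.68). Low genes were therefore measured least precisely in CLI. CLI replicate 7, at 0.85 M reads, had a mean of 21.8 TPM over olfactory receptor genes, against 1.34 ± 1.13 in Control.

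The ribosomal RNA of mitochondria took a share of TPM that differed between groups. It was 7.37% ± 4.99 in Control, 16.5% ± 12 in IC, 17.4% ± 11.6 in IC-post and 25.6% ± 12.1 in CLI (SD, n = 10 each). CLI lay above Control by 18.2 percentage points (SE 4.15, two-sided permutation p = 6.6e-04). The 13 messenger RNAs of the mitochondrial genome went the other way, from 15.1% ± 3.11 of TPM in Control to 10.1% ± 3.16 in CLI, a difference of -5.03 points (SE 1.401, two-sided permutation p = 0.00258). Part of this difference follows from the fixed total of TPM, in which a larger ribosomal share lowers every other share.

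**Figure D1:**
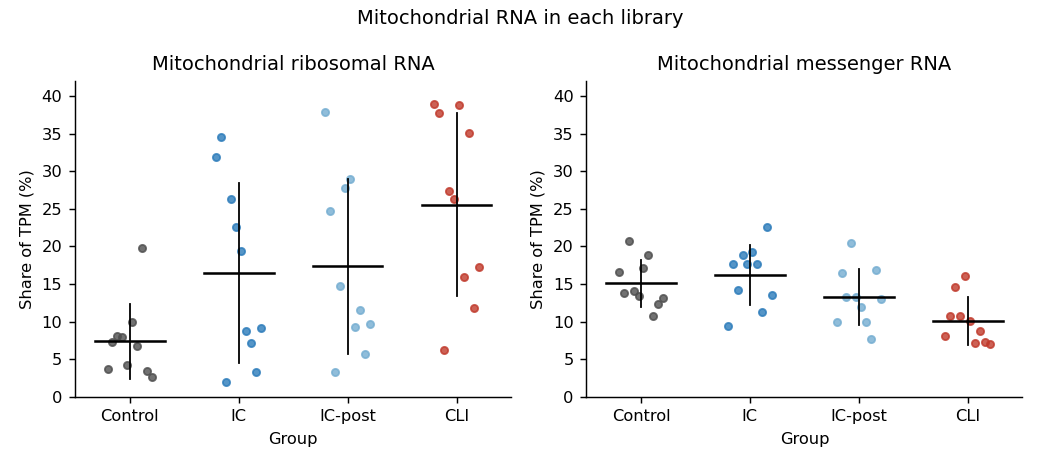
Share of TPM (%) taken by mitochondrial ribosomal RNA (left) and by mitochondrial messenger RNA (right) in each library of the 4 groups. Points are libraries, horizontal lines means and vertical lines ± 1 SD; the ribosomal share averaged 7.37% in Control and 25.6% in CLI, and the messenger share 15.1% and 10.1%.

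In CLI muscle, genes of energy metabolism and of slow fibres fell against Control, while subunits of the muscle acetylcholine receptor rose. VEGFA, the main angiogenic growth factor, went from 38.04 ± 14.6 TPM in Control to 13.3 ± 8.03 in CLI (SD, n = 10 each), a log2 change of -1.54 ± 0.25 (SE, adjusted p = 4.23e-04), and lay below the Control mean in 10 of 10 CLI libraries. HK2, the hexokinase of muscle, fell from 51.4 ± 30.6 to 7.49 ± 5.79 TPM (-2.57 ± 0.36). CHRNA1, the alpha subunit of the acetylcholine receptor, rose from 30.8 ± 49.6 to 75.3 ± 55.9 TPM (1.68 ± 0.44, adjusted p = 0.00941) and lay above the Control mean of log2 values in 10 of 10 CLI libraries. The comparison asks how limb-threatening ischemia alters muscle, and the series as titled is concerned with genes that hypoxia induces. VEGFA (ENSG00000112715) lies on chromosome 6 at 43770184 to 43786487 (hg38), HK2 (ENSG00000159399) on chromosome 2 at 74833981 to 74893359 and CHRNA1 (ENSG00000138435) on chromosome 2 at 174747592 to 174787935.

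Of 6883 genes tested, 87 rose and 1432 fell in CLI against Control, so that 94.3% of the changed genes fell; without Control replicate 8, 146 rose and 1515 fell. The median of all genes was -0.27 log2 on the deposited scale. With TMM scaling, which brings that median to 0.01, 596 genes rose and 624 fell (51.1%). The balance turns with the scaling: over nuclear protein-coding genes, a scaling chosen after the values were seen (median 0.21), 1593 rose and 348 fell, and with MT-RNR1 and MT-RNR2 left out (median 0.04) 602 rose and 471 fell. The list tests below compare a list with the other genes and so are relative to this shift. The genes given with a value in this comparison passed in the same direction with TMM, except MT-ATP6 (adjusted p = 0.126); over nuclear protein-coding genes MT-ATP6, NR4A3 and KDR did not pass (adjusted p = 0.301, 0.0587 and 0.108).

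The respiratory chain fell broadly. Of 37 nuclear genes of complex I, 31 fell and none rose (36 fell adjusted over the list alone); their mean against other genes was -0.61 log2 (camera adjusted p = 4.82e-12; adjusted p = 0.410 with an estimated correlation). Of 37 nuclear genes of complexes III, IV and V, 34 fell (35 adjusted over the list alone; mean against other genes -0.80, camera adjusted p = 6.48e-13, adjusted p = 0.410 with an estimated correlation). ATP5MC3 (ENSG00000154518, chromosome 2 at 175176258 to 175184607), a subunit of the membrane ring of ATP synthase, fell from 126 ± 44.3 to 36.8 ± 20.4 TPM (-1.79 ± 0.27, adjusted p = 3.44e-04). NDUFB10 of complex I fell by 1.73 ± 0.29 and UQCR10 of complex III by 1.54 ± 0.24. With TMM scaling, 22 and 28 members of these lists fell. All 21 tested genes of the TCA cycle fell, adjusted over the list alone as well, and 19 with TMM (mean -0.79, camera adjusted p = 4.82e-12; adjusted p = 0.410 with an estimated correlation), among them SDHB, a subunit of succinate dehydrogenase (-1.19 ± 0.22). Of the 13 genes of the mitochondrial genome, 7 fell (9 adjusted over the list alone; camera adjusted p = 0.0166, adjusted p = 0.573 with an estimated correlation) and 0 did so with TMM. MT-ATP6, which overlaps MT-ATP8 and so is uncertain, fell by 0.89 ± 0.24 on the deposited scale. The share of mitochondrial ribosomal RNA moved with this comparison, at 18.2 points higher in CLI.

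Genes of fuel use fell as well. Of 22 genes of fatty acid uptake and oxidation, 18 fell (18 fell and 1 rose adjusted over the list alone, 14 fell with TMM; camera adjusted p = 3.65e-06, adjusted p = 0.410 with an estimated correlation). FABP3, the fatty acid binding protein of muscle, fell by 2.34 ± 0.39, LPL, which frees fatty acids from lipoproteins, by 1.97 ± 0.38 and ACADM by 1.26 ± 0.21. Of 16 genes of glycolysis, 11 fell (11 adjusted over the list alone, 10 with TMM; camera adjusted p = 2.95e-04, adjusted p = 0.410 with an estimated correlation), including ENO3, the muscle form of enolase (-1.93 ± 0.37), and PGAM2, that of phosphoglycerate mutase (adjusted p = 0.00249). Of 12 genes of glycogen metabolism, 9 fell (11 adjusted over the list alone, 6 with TMM; camera adjusted p = 2.73e-04, adjusted p = 0.431 with an estimated correlation), with GYS1, glycogen synthase, at -1.34 ± 0.31 and PHKA1 at -1.43 ± 0.26. PPARGC1A, a coactivator of mitochondrial biogenesis, fell by 1.32 ± 0.22, and PERM1, which acts with it in muscle, by 2.34 ± 0.34. CKMT2, the mitochondrial creatine kinase, fell by 2.27 ± 0.36, and GPT2, a mitochondrial alanine transaminase, was at -2.40 ± 0.32.

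Of 23 hypoxia-induced genes, 10 fell and 2 rose (11 and 2 adjusted over the list alone). The genes that fell were TFRC, HK2, VEGFA, VLDLR, ALDOA, LDHA, PLIN2, PGK1, EGLN1 and P4HA1, listed in full after their values were seen. Among them, HK2, ALDOA, LDHA and PGK1 are also in the glycolysis list and VEGFA in the angiogenic list. PFKFB3, which makes an activator of glycolysis, rose (1.29 ± 0.43), and so did HMOX1, heme oxygenase (0.94 ± 0.33), which was named after its value was seen. TFRC, the transferrin receptor, fell by 2.25 ± 0.30. As a list these genes did not differ from other genes (camera adjusted p = 0.139, adjusted p = 0.650 with an estimated correlation), while fry placed them lower on balance (adjusted p = 0.00227). Camera called them lower with a filter of 1 TPM (mean -0.54, adjusted p = 2.67e-07), with nuclear protein-coding scaling (adjusted p = 0.0135) and with TMM without CLI replicate 7 (adjusted p = 0.0462), all chosen after the values were seen, but not with TMM of all libraries (adjusted p = 0.0662). Of 13 angiogenic factors and receptors, 8 fell (9 adjusted over the list alone; camera adjusted p = 0.0204, adjusted p = 0.569 with an estimated correlation), VEGFB by 1.41 ± 0.33 and the VEGF receptor KDR by 0.92 ± 0.24. EPAS1, an oxygen-regulated transcription factor, also fell (adjusted p = 0.00177). With TMM scaling, 6 hypoxia-induced genes fell and 2 rose, and 4 angiogenic genes fell.

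Of 12 genes of the slow-fibre sarcomere, 9 fell (12 adjusted over the list alone, 7 with TMM; mean -1.12, camera adjusted p = 9.53e-05, adjusted p = 0.410 with an estimated correlation). MYL3 (ENSG00000160808, chromosome 3 at 46857872 to 46882169), a myosin light chain of slow fibres, fell from 692 ± 357 to 160 ± 154 TPM (-2.36 ± 0.51). MYH7B fell by 2.07 ± 0.40, and ANKRD2, a stretch-responsive protein of slow fibres, by 2.70 ± 0.62. Of 13 genes of the fast-fibre sarcomere, 5 fell as well (5 adjusted over the list alone, 2 with TMM; mean -0.62), though camera did not call that list (adjusted p = 0.115, adjusted p = 0.650 with an estimated correlation, 0.0137 with TMM); MYH2, the myosin of fast oxidative fibres, fell by 1.81 ± 0.48. Of 12 genes of denervation and the neuromuscular junction, 4 rose and none fell (4 adjusted over the list alone, 4 with TMM; mean 0.93, camera adjusted p = 6.69e-07, adjusted p = 0.410 with an estimated correlation). They were CHRNA1, CHRND (1.22 ± 0.35), CHRNG, the subunit of the fetal receptor (1.66 ± 0.53), and GADD45A, a growth arrest gene (ENSG00000116717, chromosome 1 at 67685061 to 67688338; 2.10 ± 0.44). In 1 Control library, replicate 8, CHRNA1 was at 171 TPM.

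Of 12 immediate early genes, FOS rose (2.21 ± 0.67) and NR4A3 fell by 1.84 ± 0.52; adjusted over the list alone 5 rose and 2 fell (camera adjusted p = 5.91e-05, adjusted p = 0.410 with an estimated correlation, 0.0501 with TMM and 0.324 with nuclear protein-coding scaling). The mean of FOS in CLI rested on 3 libraries, replicates 2, 6 and 8, at 341, 284 and 471 TPM; the other 7, at 11.39 to 25.36 TPM, lay within the range of Control (2.89 to 30.73). Those 3 libraries held 35.1% to 38.8% mitochondrial ribosomal RNA, and CLI replicate 1, at 39.0%, had FOS at 12.4 TPM. SAA1, an acute phase protein with a near-identical copy and so uncertain, rose by a log2 value of 2.64 ± 0.90 (adjusted p = 0.0381). The metallothionein MT2A (1.43 ± 0.46) and the elongation factor EEF1A1 (0.92 ± 0.29), uncertain for the same reason, also rose. Markers of several other cells fell: 9 of 15 fibro-adipogenic and fibroblast markers (11 adjusted over the list alone, 6 with TMM; camera adjusted p = 6.85e-04, adjusted p = 0.431 with an estimated correlation), with DPT at -2.11 ± 0.35 and CLEC3B at -2.45 ± 0.42, 4 of 9 adipocyte markers (9 adjusted over the list alone, 3 with TMM; 0.00509, and 0.410 with an estimated correlation as adjusted p), 7 of 17 endothelial markers (8 adjusted over the list alone, 3 with TMM; 0.0461 and 0.637) and 7 of 18 matrix genes (8 adjusted over the list alone, 2 with TMM; 0.0247 and 0.630). Without CLI replicate 7 camera no longer called the endothelial and matrix lists (adjusted p = 0.0914 and 0.0825). Of 13 pericyte and vascular smooth muscle markers 6 fell (9 adjusted over the list alone, 3 with TMM) with no call of the list (camera adjusted p = 0.110, adjusted p = 0.573 with an estimated correlation, 0.0390 with TMM), and of 6 macrophage and monocyte markers 0 passed, also adjusted over the list alone (median -0.41, mean -0.02, a test direction above other genes, camera adjusted p = 0.791).

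Camera called 21 of 32 lists, and none with an estimated correlation, while 20 single omissions of a library left between 1122 and 2110 changed genes. With the share of mitochondrial ribosomal RNA as a covariate, limma called 0 genes (lowest adjusted p = 0.451), VEGFA changing by -0.77 ± 0.30 and CHRNA1 by 0.78 ± 0.62; camera still called the lists of complex I (mean -0.33, adjusted p = 1.60e-08), complexes III, IV and V (-0.42, 7.47e-11), the TCA cycle (-0.45, 3.80e-11) and slow fibres (-0.72, 3.62e-06) lower, all 4 at an adjusted p of 0.205 with an estimated correlation, but no longer called the denervation list (0.42, adjusted p = 0.0939) and the immediate early list (-0.03, adjusted p = 0.538). The covariate and the group are nearly confounded, since 1 Control library had 10% or more and 1 CLI library less.

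**Figure D2:**
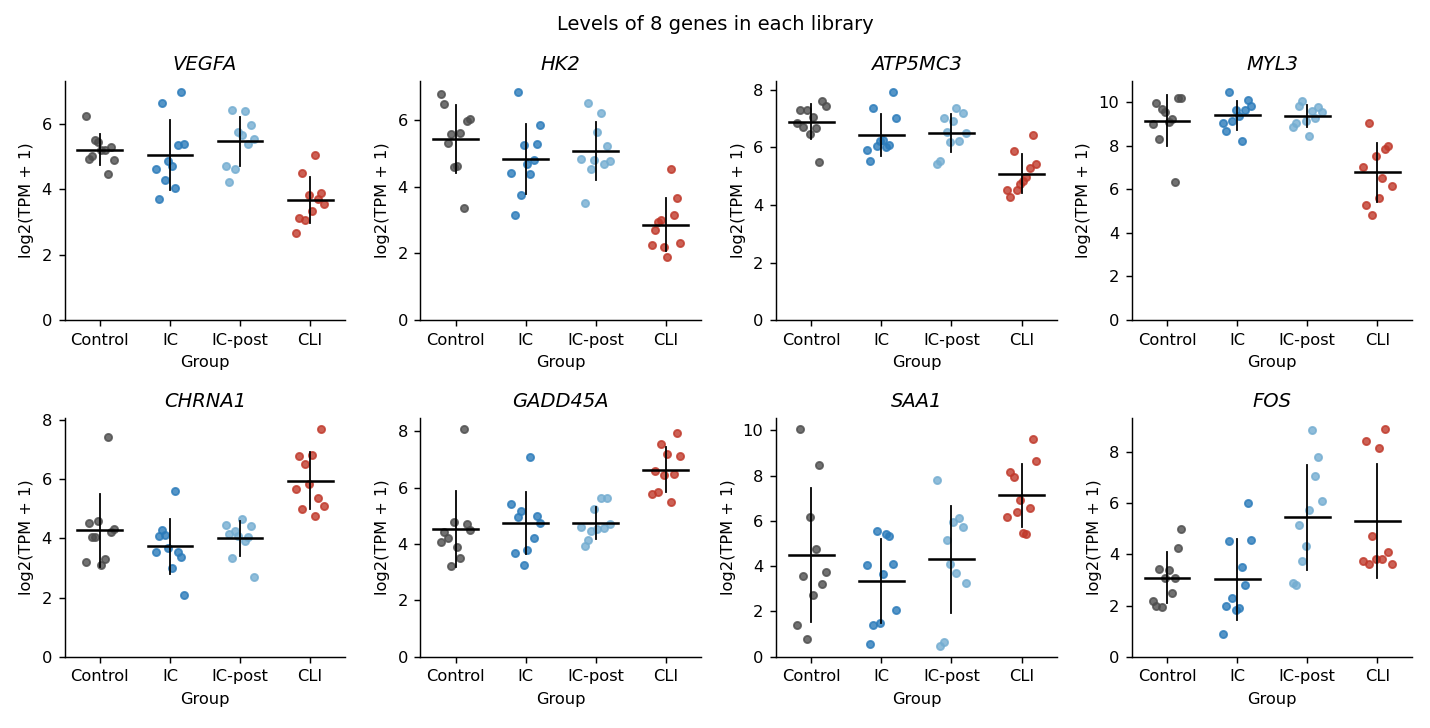
log2(TPM + 1) of 8 genes in each library of the 4 groups, with points for libraries, horizontal lines for means and vertical lines for ± 1 SD. VEGFA, HK2 and ATP5MC3 lie below the Control mean in 10 of 10 CLI libraries, and CHRNA1 above it in 10 of 10.

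Set against claudicants, CLI muscle again had lower sarcomere and mitochondrial genes and higher receptor subunits. MYL3 fell from 743 ± 329 TPM in IC to 160 ± 154 in CLI (-2.62 ± 0.43, adjusted p = 4.80e-04, SD and n = 10 each) and lay below the IC mean in 10 of 10 libraries. CHRNA1 rose from 15.1 ± 12.4 to 75.3 ± 55.9 TPM (2.22 ± 0.37, adjusted p = 4.92e-04), and SAA1 (ENSG00000173432, chromosome 11 at 18266174 to 18269977) from 17.7 ± 17.9 to 216 ± 232 TPM (3.77 ± 0.61), both above the IC mean in 10 of 10 libraries. The comparison tests whether the stages of the disease differ.

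In all, 136 genes rose and 114 fell (45.6%), 178 of them by at least 1 log2, with a median of 0.13 over all genes. TMM scaling gave 312 rises and 507 falls (61.9%), while nuclear protein-coding scaling (median 0.36) gave 2345 rises and 244 falls, and leaving out MT-RNR1 and MT-RNR2 (median 0.29) gave 1552 and 223. Slow-fibre genes fell in 9 of 12 cases (10 adjusted over the list alone; mean -1.56, camera adjusted p = 3.34e-16, adjusted p = 0.123 with an estimated correlation), including MYH7, the slow myosin heavy chain (-1.70 ± 0.37). The fast-fibre list was lower too (1 of 13 fell, 2 adjusted over the list alone and 3 with TMM; mean -0.71, camera adjusted p = 7.59e-05, adjusted p = 0.338 with an estimated correlation, 0.473 with quantile normalization). NMRK2, a kinase of nicotinamide riboside, fell by 3.11 ± 0.56, COQ10A fell by 1.93 ± 0.27 and CKMT2 fell by 2.09 ± 0.37. For complexes III, IV and V, 6 of 37 nuclear genes fell (33 adjusted over the list alone and 29 with TMM; mean -0.98, camera adjusted p = 6.47e-25, adjusted p = 0.155 with an estimated correlation), ATP5MC3 by 1.34 ± 0.30. For complex I, 2 of 37 fell (14 adjusted over the list alone and 20 with TMM; 2.05e-16 and, with an estimated correlation, adjusted p = 0.177), NDUFB10 by 1.38 ± 0.30. For the TCA cycle, 3 of 21 fell (18 adjusted over the list alone and 19 with TMM; 1.77e-16 and, with an estimated correlation, adjusted p = 0.177), SUCLG1 by 1.09 ± 0.28. Of the 13 mitochondrial genome genes 2 fell (11 adjusted over the list alone; 5.84e-09 and, with an estimated correlation, adjusted p = 0.177), MT-CO1 by 0.92 ± 0.24.

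The 4 members of the denervation list that rose were CHRNA1, CHRND (1.59 ± 0.28), CHRNG (2.21 ± 0.45) and GADD45A (1.91 ± 0.38), out of 12 (6 adjusted over the list alone; camera adjusted p = 2.55e-05, adjusted p = 0.155 with an estimated correlation). Of 23 hypoxia-induced genes 3 fell, HK2 (-1.97 ± 0.36), VEGFA (-1.38 ± 0.35) and TFRC (-1.51 ± 0.40), and none rose (5 fell and 1 rose adjusted over the list alone). The median of that list was 0.15 while its mean against other genes was -0.31 and camera placed it lower (adjusted p = 0.0245, adjusted p = 0.593 with an estimated correlation, 0.0563 with TMM). Of 16 glycolysis genes 4 fell and PFKP, the platelet phosphofructokinase, rose (1.46 ± 0.31), with 9 falls adjusted over the list alone (camera adjusted p = 8.91e-07, adjusted p = 0.271 with an estimated correlation). FBXO30, a ubiquitin ligase of muscle atrophy, rose (1.15 ± 0.29) while FBXO40, another muscle ligase, fell by 1.33 ± 0.28. SOCS3, an inhibitor of cytokine signalling, was the immediate early list's 1 rise of 12 (2.10 ± 0.49; 6 adjusted over the list alone; camera adjusted p = 0.00219, adjusted p = 0.467 with an estimated correlation and 0.297 with nuclear protein-coding scaling). MDM2, which restrains p53, rose (1.53 ± 0.35), as did CCN1, a matrix signalling protein (1.82 ± 0.38). Markers of other cells lay lower beside the muscle genes: 17 endothelial (0 passed, also adjusted over the list alone, and 4 fell with TMM; mean -0.46, camera adjusted p = 5.26e-04, adjusted p = 0.453 with an estimated correlation), 9 adipocyte (1 fell, 2 adjusted over the list alone; mean -0.54, camera adjusted p = 0.00576, adjusted p = 0.162 with an estimated correlation, 0.0657 with TMM) and 15 fibro-adipogenic and fibroblast markers (0 passed, 2 fell adjusted over the list alone; mean -0.31, camera adjusted p = 0.0320, adjusted p = 0.607 with an estimated correlation, 0.141 with TMM).

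Without IC replicate 5 there were 154 changed genes (82 rose and 72 fell), without IC replicate 6 164 (82 and 82) and without IC replicate 7 789 (534 and 255), against 250. The balance of directions turned without CLI replicate 3 (127 rose and 198 fell), CLI replicate 9 (103 and 141) and IC replicates 1 (97 and 111), 2 (94 and 132) and 4 (106 and 109). Falls numbered 73, 67 and 66 without CLI replicates 1, 2 and 6, and 68, 67 and 70 without IC replicates 3, 9 and 10. With the share of mitochondrial ribosomal RNA as a covariate there were 2144 (2011 rose and 133 fell), while the median of all genes went from 0.13 to 0.38. The added calls were thus mostly rises that go with a shift of all genes. HK2 at -1.49 ± 0.31, VEGFA at -0.80 ± 0.25 and CHRNA1 at 2.18 ± 0.42 were past the threshold, and camera no longer called the immediate early list (adjusted p = 0.292).

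**Figure D3:**
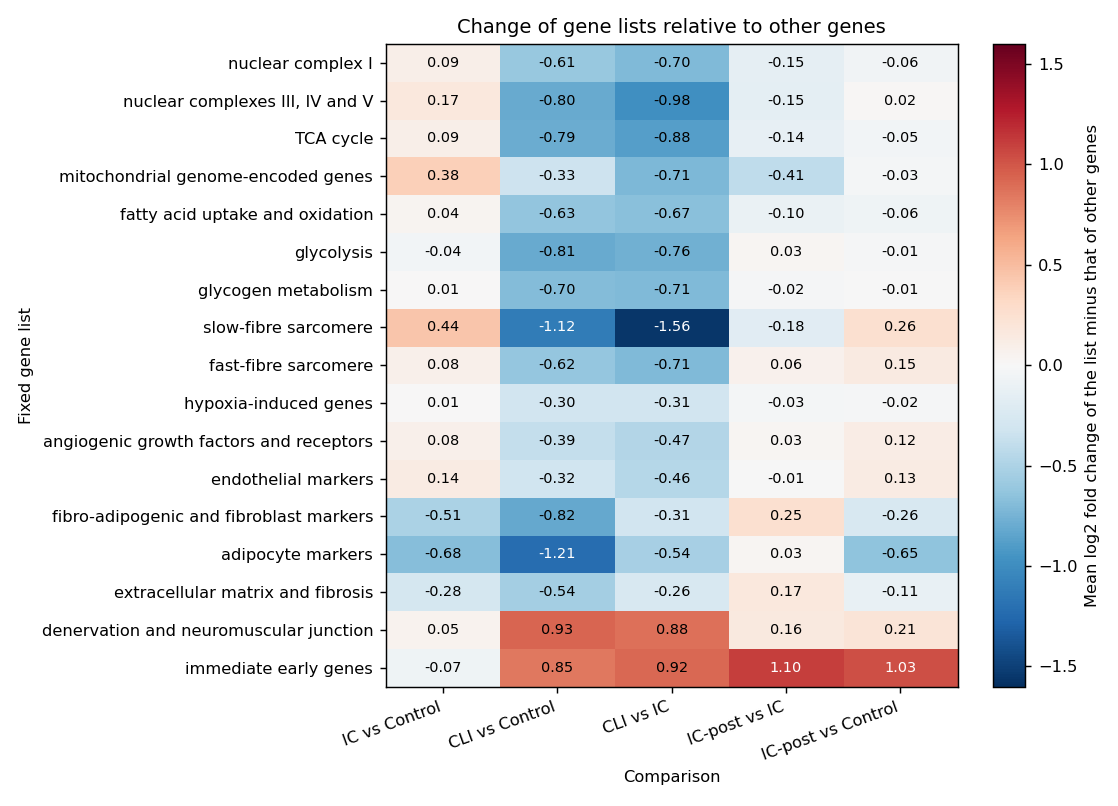
Mean log2 fold change of each fixed gene list minus that of the other genes, for the 5 comparisons, as numbers and on a colour scale from blue (lower) to red (higher). The slow-fibre list is at -1.12 in CLI against Control and -1.56 in CLI against IC, and the immediate early list at 1.10 in IC-post against IC.

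Claudicant muscle before treatment held no gene that passed against Control. The mitochondrial genome's genes and slow-fibre genes lay above other genes by a mean log2 value of 0.38 and 0.44 (-0.018 and 0.23 with quantile normalization). The comparison asks what claudication alters in muscle before revascularization. Limma called 0 of 6883 genes (lowest adjusted p = 0.0515), while 11 lay higher and 2624 lower at an unadjusted p under 0.05. With TMM scaling 0 passed (241 higher and 115 lower unadjusted) and voom called 0, while array weights gave 6105 (35 rose and 6070 fell). The median of all genes was -0.39 log2, and 96.8% of genes lay below 0. MYL6B, a slow-fibre light chain, was at 0.77 ± 0.32 (adjusted p = 0.117) and PFKFB3 at 0.62 ± 0.34. AMOT, a regulator of endothelial movement, was at -0.84 ± 0.18 (adjusted p = 0.104) and the peroxiredoxin PRDX1 at -0.78 ± 0.19.

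Relative to the shift, the 13 genes of the mitochondrial genome were higher as a list (0 of 13 passed, also adjusted over the list alone; camera adjusted p = 2.25e-15, adjusted p = 0.162 with an estimated correlation), as were 12 slow-fibre genes (0 passed; 4.18e-14 and, with an estimated correlation, adjusted p = 0.115). Nuclear complexes III, IV and V (mean 0.17, median -0.20), ribosomal proteins (0.21, -0.14) and endothelial markers (0.14, -0.23) were called higher than other genes with medians below 0 (camera adjusted p = 6.92e-08, 1.87e-10 and 2.62e-04; adjusted p = 0.714, 0.494 and 0.714 with an estimated correlation); endothelial markers were not called with TMM (adjusted p = 0.109). With quantile normalization camera no longer called the genes of the mitochondrial genome, complexes III, IV and V and endothelial markers (adjusted p = 0.738, 0.141 and 0.0547). The medians of the mitochondrial genome and slow-fibre lists were themselves 0.086 and 0.0034 log2, and fry called neither (fry adjusted p = 0.801 for both). Fibro-adipogenic markers were lower (median -0.90; 0 of 15 passed, 11 adjusted over the list alone; camera adjusted p = 5.74e-04, adjusted p = 0.714 with an estimated correlation). Hypoxia-induced genes had a median of -0.44 and a mean of 0.01 against other genes (0 of 23 passed, camera adjusted p = 0.254), and angiogenic genes of -0.32 and 0.08 (0 of 13, 0.0643). Mitochondrial ribosomal RNA was at 16.5% in IC and 7.37% in Control. Without IC replicate 7 limma called 3171 genes, without IC replicates 8 or 9 it called 1 and 3, and without Control replicates 8 or 9 it called 5 and 1.

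The fold changes of CLI and of IC against the same controls correlated across genes at r = 0.264, with a covariance of 0.0289. Simulated groups with no effect against the same controls gave a median r of 0.469 (-0.02 to 0.79 in 100 draws) and a mean covariance of 0.0243. With the controls split between the comparisons, r was 0.00983. No gene was called in both, since IC had no calls. Genes are not independent replicates.

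At 6 months after revascularization, no gene passed against the same patients before it, but the immediate early genes, which cells switch on within minutes of a stimulus, lay higher as a list. FOS was at 13.6 ± 18.9 TPM before and 101 ± 142 after (SD, n = 10 each; log2 change 2.42 ± 0.67, adjusted p = 1.00) and higher than the IC mean in 8 of 10 libraries. The comparison asks what restoring blood flow alters. Limma called 0 genes (lowest adjusted p = 1.00), with 76 higher and 8 lower at an unadjusted p under 0.05. It called 0 with TMM (48 and 89), 0 with voom, and 0 with the replicate number as a block (421 at an unadjusted p under 0.05). With array weights it called 5208 (5175 rose and 33 fell), unlike the other alternatives. Of 12 immediate early genes, 0 passed over all genes and 9 adjusted over the list alone (10 with the block). Their mean was 1.10 log2 above other genes (camera adjusted p = 1.29e-22, adjusted p = 0.0454 with an estimated correlation). With the block camera gave an adjusted p of 1.14e-13 and, with an estimated correlation, adjusted p = 0.270. EGR1 (ENSG00000120738, chromosome 5 at 138465490 to 138469315) was at 1.71 ± 0.53, JUNB at 1.49 ± 0.48, FOSB at 1.48 ± 0.47, and DUSP1, a phosphatase of the same response, at 0.90 ± 0.34.

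**Figure D4:**
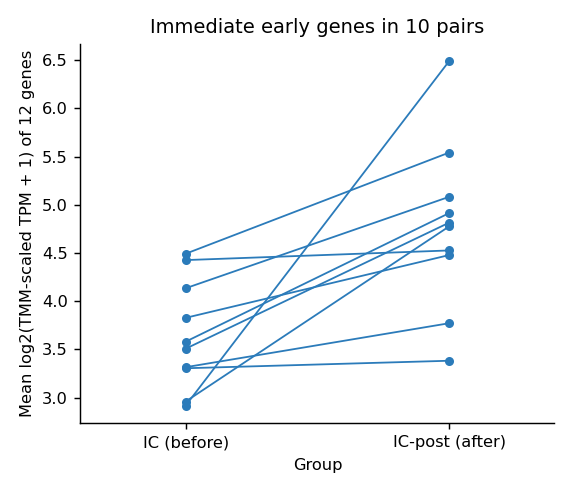
Mean log2(TMM-scaled TPM + 1) of 12 immediate early genes for each of 10 pairs of IC (before) and IC-post (after) libraries, joined by lines. The mean is higher after revascularization in 10 of 10 pairs, by 1.13 log2 on average.

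The 13 genes of the mitochondrial genome lay lower (median -0.28, 0 passed; camera adjusted p = 2.59e-20, adjusted p = 0.0623 with an estimated correlation), MT-CO2 at -0.37 ± 0.22. Nuclear complex I and complexes III, IV and V had means of -0.15 each against other genes (camera adjusted p = 4.92e-07 and 3.32e-07, adjusted p = 0.898 for both with an estimated correlation). Slow-fibre genes were also called lower (median -0.08, 0 of 12 passed, camera adjusted p = 1.23e-04, adjusted p = 0.868 with an estimated correlation). Fibro-adipogenic and fibroblast markers were called higher (median 0.36, mean 0.25, 0 of 15 passed, camera adjusted p = 0.00447, adjusted p = 0.980 with an estimated correlation). Hypoxia-induced genes were at a median of 0.14 and a mean of -0.03 (0 of 23 passed, camera adjusted p = 0.374), and angiogenic genes at 0.10 and 0.03 (0 of 13, 0.866), with VEGFA at 0.41 ± 0.36. The 87 genes that rose in CLI were higher here (mean 0.09, camera adjusted p = 0.0148, adjusted p = 0.639 with an estimated correlation). The 200 of smallest p that fell in CLI were lower against other genes (-0.04, camera adjusted p = 0.00652, adjusted p = 0.639 with an estimated correlation), though their median was 0.05.

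Against Control, IC-post muscle showed higher FOS, EGR1 and JUNB and a broad lower level of other genes. FOS rose from 9.67 ± 8.68 TPM to 101 ± 142 (2.37 ± 0.63, SD and n = 10 each; adjusted p = 0.0424). EGR1 (1.62 ± 0.47, adjusted p = 0.0454) and JUNB (1.47 ± 0.40, adjusted p = 0.0434) rose and were higher than the Control mean in 9 of 10 libraries. The comparison asks how far treated muscle remains from muscle without the disease. Over all genes, 7 rose and 581 fell (98.8%), with a median of -0.27; with TMM, limma called 0 (577 higher and 439 lower at an unadjusted p under 0.05), and voom called 10. FOS, EGR1 and JUNB had an adjusted p of 0.0859 with TMM. Of 12 immediate early genes, these 3 rose, also adjusted over the list alone (mean 1.03; camera adjusted p = 2.75e-17, adjusted p = 0.0704 with an estimated correlation). The ferritin FTH1 fell by 0.85 ± 0.24 (uncertain, with many pseudogenes), VIM by 0.80 ± 0.24, PRDX1 by 0.69 ± 0.19 and HADHA, of fatty acid oxidation, by 0.66 ± 0.20, none past the threshold with TMM. Genes of developing muscle lay above other genes (mean 0.42; 1 of 11 fell, VIM; camera adjusted p = 1.06e-05, adjusted p = 0.153 with an estimated correlation, 0.0609 with TMM). Slow-fibre genes had a median of -0.14 and a mean of 0.26 (0 of 12 passed; 4.11e-04 and, with an estimated correlation, adjusted p = 0.679, with TMM 0.0502). Hypoxia-induced genes had a median of -0.37, a mean of -0.02 and a test direction above other genes (0 of 23, camera adjusted p = 0.551), and of 13 angiogenic genes 1 fell (median -0.18, mean 0.12, 0.0617). Mitochondrial ribosomal RNA was at 17.4% in IC-post.

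The count of 588 rested on single libraries. Leaving out IC-post replicates 1, 2, 3, 4, 5, 6, 7, 9 or 10 gave 22, 20, 1627, 0, 0, 23, 2217, 911 and 306 genes, and leaving out Control replicates 1, 2, 3, 4, 5, 6, 9 or 10 gave 0, 0, 40, 0, 12, 971, 53 and 25. No gene rose, FOS, EGR1 and JUNB included, in 12 of the 20 omissions of a library, those of IC-post replicates 1, 2, 4, 5 and 6 and of Control replicates 1, 2, 3, 4, 5, 9 and 10, nor with the replicate block (0 rose and 4 fell). In the other 8 omissions 3 to 14 genes rose, against 7 in all libraries; FOS and JUNB passed in all 8 and EGR1 in 5.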

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

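The tests that leave out CLI replicate 7, that use markers of other cells, that use the share of mitochondrial messenger RNA and that take the medians of IC-post against Control were chosen after the results were seen, as were the bootstrap errors and the covariate of mitochondrial ribosomal RNA. The contrast of oxidative phosphorylation genes within IC-post and the relations of small nuclear RNAs in IC-post and Control were not set before either; the tests of IC medians, the contrast within IC, the relation in CLI and the splits of the libraries were.

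Of 202 sets of 10 libraries examined for named genes, 22 had a library far from the others, and of 24 sets of library measures 4 did; chance flags about 1 in 20 groups. Of these 26 values, 15 came from Control replicate 8. In TPM, that library was far below the other controls for ACADM (39.16, nearest 68.26), CKMT2 (174.6), FBXO40 (94.78), FTH1 (617.9), MYL3 (78.47), NDUFB10 (144.7), PPARGC1A (15.25), SDHB (104.4) and SMCO1 (5.544). It was far above them for CHRNA1 (171, nearest 23.13), CHRND (119.9), CHRNG (158.1), GADD45A (269, nearest 26.51) and PRDX1 (472.2). Its mitochondrial ribosomal RNA share of 19.8% was also far above the nearest control at 9.9%. These directions are those of CLI for CHRNA1, CHRND, CHRNG, GADD45A, MYL3, CKMT2, NDUFB10, PPARGC1A, SDHB, ACADM, SMCO1 and FBXO40. Without this library, CLI against Control gave 1661 changed genes, and its label was not tested.

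ANKRD2 stood apart at 4360 TPM in Control replicate 7, STRIT1 at 857 in Control replicate 6, and CASQ1 at 209.3 in CLI replicate 7. MYH2 stood apart at 2536 TPM in IC replicate 4 and at 266.3 in CLI replicate 6. HBA2 was at 16.41 TPM in IC-post replicate 1, MDM2 at 89.87 in IC replicate 7 and TNNC1 at 25053 in IC replicate 7. IC replicate 3 was estimated at 30.22 M reads, far above the other IC libraries. CLI replicate 7 had a mean olfactory receptor level of 21.788 TPM and 26158 genes above 10 TPM, where the nearest CLI library had 8387. The change against Control differed between CLI and IC for 250 genes, by the direct test of CLI against IC.

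Near-uniform lower levels in IC and IC-post against Control were the first pattern weighed. With MT-RNR1 and MT-RNR2 left out and the libraries rescaled, the median of IC against Control was still -0.24 (bootstrap SE 0.079). This argues against their direct share of the total as the whole cause there. The median of IC-post against Control went from -0.27 to -0.106 (SE 0.064), which leaves that share open in IC-post. In libraries with under 10% mitochondrial ribosomal RNA, the medians were -0.012 (5 IC against 9 Control) and 0.016 (4 IC-post against 9 Control). The lower levels thus went with the libraries rich in that RNA, in a subset chosen after the values were seen. What else sets those libraries apart was not tested. Without the 100 most abundant genes the medians were -0.034 and -0.0051. Those genes took 67.3% ± 8.76 of TPM in IC and 65.6% ± 6.45 in IC-post against 58.8% ± 1.74 in Control (SD, n = 10 each). A few genes taking a larger share of a fixed total would give this. Of the 100 genes 15 are mitochondrial, and mitochondrial ribosomal RNA (16.5% in IC, 17.4% in IC-post, 7.37% in Control) counts towards their share. Their share is thus not a cause separate from that RNA. A change in the 100 genes in claudication stays open and was not tested.

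Lower oxidative phosphorylation genes in CLI were the second. With TMM, 74 nuclear genes averaged -0.72 log2 in CLI against Control (SE 0.14), whereas IC libraries with 10% or more mitochondrial ribosomal RNA lay 0.148 above the other IC libraries (SE 0.234, 5 against 5, exact permutation p = 0.56) and those of IC-post 0.107 below the others (SE 0.106, 6 against 4, p = 0.35; both 0.56 adjusted), which argues against that RNA as the whole cause. The covariate moved the median of the 74 genes from -0.99 (median SE 0.24) to -0.34 (0.30) against Control, where group and covariate nearly coincide, and from -0.82 (0.30) to -0.49 (0.26) against IC, but it also raised that of all genes, from -0.27 to 0.05 and from 0.13 to 0.38, and camera still placed complex I and complexes III, IV and V below other genes in both (means -0.33 and -0.42 against Control, -0.66 and -0.91 against IC). Without CLI replicate 7, 51 of 74 genes fell with TMM, which argues against that library as the cause. With all libraries and TMM, 60 markers of 5 other cell types had a median of -0.52 (-1.35 to -0.13 by cell type). The SE of that median, 0.06, came from drawing genes and not libraries, so it is too small where genes move together. Of these markers 15 fell and 0 rose, which argues against fewer fibres among these 5 cell types. It says less for macrophages and monocytes, where 0 of 6 markers fell, and for adipocytes, whose marker LPL is also in the fatty acid list. Cells outside these types, such as lymphocytes, were not in this set, so a larger part of them was not tested here. A part played by RNA composition and an effect of the disease both stay open, and the latter is a hypothesis.

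A higher share of mitochondrial ribosomal RNA in CLI was the third. Mitochondrial messenger RNA was -5.03 points of TPM different, which argues against more mitochondrial RNA of every kind. The level of 9 spliceosomal small nuclear RNAs rose with the share across CLI libraries (r = 0.739, permutation p = 0.0142, adjusted 0.0213 over 3 relations; rho = 0.806, p = 0.00719, adjusted 0.0110; r = 0.745 without the 2 farthest) and across IC-post libraries (r = 0.879, p = 0.00116, adjusted 0.00348; rho = 0.806, p = 0.00734, adjusted 0.0110; r = 0.893). In Control r was 0.298 (permutation p = 0.398, rho = 0.370 with p = 0.295, r = 0.139 without the 2 farthest). In IC none was computed, because its shares form a pair of clusters with a gap from 9.1% to 19.4%. Shares in IC-post and CLI also have gaps, from 14.7% to 24.7% and from 17.3% to 26.3%, so their relations may rest in part on clusters. The relations in CLI and IC-post are those that structured RNA carried into libraries together would give. Depletion or RNA quality may be its source, and neither was measured.

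For CLI against Control chance is unlikely, though 100 splits cannot exclude it. With the real one included, 2 of 100 splits gave at least 1519 genes, the highest other giving 3145. With TMM 1 did (1220, highest other 189). The split with 3145 genes separated libraries by 18.4 points of mitochondrial ribosomal RNA, close to the real 18.2, and its many calls point to a structure of the samples. The count on the deposited scale therefore does not by itself set the real grouping apart. The highest splits of IC (9.67 points, real 9.16) and IC-post (10.3, real 9.98) against Control also called many genes, but splits of 10.6 and 10.33 points for IC and of 10.19 for IC-post called 0, so the share alone does not set the count. For lists in CLI against Control, 3 of 100 splits gave at least 21 (highest other 21). For CLI against IC chance is likewise unlikely, with 1 of 100 splits giving 250 genes (highest other 2), 1 giving 819 with TMM (highest other 2) and 3 giving at least 22 lists (highest other 24). Where the real count is 0 genes, the splits test nothing for genes, since all 100 give at least that many: this holds for IC-post against IC (highest other 0) and IC against Control (highest other 2997). For their lists chance cannot be excluded: of 100 splits that part all 10 pairs of IC and IC-post, 50 gave at least the real 9 (highest other 21), and of 100 for IC against Control 48 gave at least the real 10 (highest other 19). The same holds for IC-post against Control, with 5 of 100 splits giving at least 588 genes (highest other 3276) and 66 at least 9 lists (highest other 17). The other splits of CLI against Control gave a median of 12 lists, so that lists are called often with the preset correlation.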

How the results depend on the processing

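Tests and lists were set before the data were examined; nuclear protein-coding scaling, the covariates, the filter of 1 TPM, voom, the subsets by depth or mitochondrial ribosomal RNA, TMM without CLI replicate 7, and TMM with split controls were chosen after seeing the data. The planned negative binomial fits of counts were not run, because TPM keeps no whole reads. Scaling each library to the same total tests nothing here, because the deposited totals were already equal. Where a value below moved, the cause was not tested, except that higher filters test fewer genes and subsets hold fewer libraries. Depth limits low genes in CLI most.

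Of the named genes' alternatives, 1736 of 1885 kept direction and side of the threshold in CLI against Control and 149 were weaker. In CLI against IC 1236 of 1317 did and 81 were weaker, in IC against Control 354 of 370 with 15 stronger, in IC-post against IC 503 of 515 with 12 stronger, and in IC-post against Control 205 of 454 with 249 weaker. MT-CO1 in IC against Control reversed to -0.45 with quantile normalization.

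Counts of changed genes follow. IC against Control gave 0, and 2 with pseudocount 5, 6105 with array weights, 1 with robust estimates, 1 with the replicate block and 1 with the olfactory receptor covariate. CLI against Control gave 1519, and 596 with no filter, 902 with a filter of 1 TPM, 676 with 50 TPM, 982 with quantile normalization, 4226 with array weights, 781 with the olfactory receptor covariate and 0 with the mitochondrial ribosomal RNA covariate. CLI against IC gave 250, and 140 with a filter of 50 TPM, 819 with TMM, 703 with quantile normalization, 847 with all 40 libraries in one fit, 3042 with array weights, 645 with the replicate block, 2589 with nuclear protein-coding scaling, 2144 with the mitochondrial ribosomal RNA covariate, 907 with voom, 125 with the olfactory receptor covariate, 2142 in libraries with 10% or more mitochondrial ribosomal RNA and 895 with TMM without CLI replicate 7. IC-post against IC gave 0, and 5208 with array weights. IC-post against Control gave 588, and 0 with no filter, with a filter of 1 TPM, with TMM, with quantile normalization, with all libraries in one fit, with nuclear protein-coding scaling and with the mitochondrial ribosomal RNA covariate, 2 with 50 TPM, 4 with the replicate block, 10 with voom, 22 without libraries under 4 M reads and 6 in libraries under 10% mitochondrial ribosomal RNA. Array weights ran from 0.0813 to 5.92. Leaving out each library gave 0 to 3171, 1122 to 2110, 154 to 789, 0 to 0 and 0 to 2217 genes in the order above.

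For the pairs of IC and IC-post, the block ended the call of immediate early genes with an estimated correlation and changed no other call of a list, nor of a gene adjusted over all genes. Adjusted over the list alone, it took the calls from 9 to 10 immediate early genes, from 0 to 1 gene of denervation and from 0 to 2 myogenic regulators. In the other comparisons no label ties samples of equal number. Median correlations of same-numbered libraries were 0.07 for Control and IC, -0.02 for Control and CLI, 0.16 for IC and CLI and 0.06 for Control and IC-post. In the same order, 2, 1, 3 and 1 of 10 were best with their own number. The share of mitochondrial ribosomal RNA went with the number outside Control. Replicates 1, 2, 4, 5 and 6 held 19.4% to 34.6% in IC, 14.7% to 37.9% in IC-post and 26.3% to 39.0% in CLI. The others held 2.0% to 9.1%, 3.3% to 11.5% and, apart from CLI replicate 8 at 35.1%, 6.2% to 17.3%. Whether the number marks shared processing was not tested.

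Lists called numbered 10, 21, 22, 9 and 9 in the same order. With an estimated correlation they were 0, 0, 0, 1 and 0. With fry they were 0 in IC against Control, 6 in CLI against IC, 0 in IC-post against IC and 0 in IC-post against Control. Of the lists that camera called lower in CLI against Control, fry called, among others, complex I, complexes III, IV and V and the TCA cycle (fry adjusted p = 3.96e-04 each). It also called slow-fibre genes lower (fry adjusted p = 0.00121). Fry takes no account of the lower median of all genes there. It did not call, among others, denervation and immediate early genes (fry adjusted p = 0.104 and 0.400). IC against Control gave 6 with quantile normalization and 5 under 10% mitochondrial ribosomal RNA. IC-post against Control gave 2 with TMM, 2 with quantile normalization, 4 with nuclear protein-coding scaling, 17 with a filter of 1 TPM and 4 under 10%. Quantile normalization also ended calls of mitochondrial genome genes in CLI against Control and CLI against IC (camera adjusted p = 0.265 and 0.229), of hypoxia-induced genes in CLI against IC (0.155), and of slow-fibre genes and genes of developing muscle in IC-post against Control (0.220 and 0.116).

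The correlation of CLI and IC changes went from 0.264 to 0.00983 with split controls and -0.012 with TMM and split controls. Genes that rose in CLI, tested in IC-post against IC, had a mean of 0.093 and were not called with an estimated correlation, nor with fry (median 0.18); genes that fell had -0.036 and were not called with an estimated correlation, and fry put them at a median of 0.051.

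For the lists chosen for report in each comparison, the direction of a test reversed as follows, and reversals of other lists are left out. Camera compares moderated t values, so its direction can differ from the sign of the mean printed here. In IC against Control, fry, which takes no account of other genes, put hypoxia-induced genes at -0.44, angiogenic genes at -0.32, complexes III, IV and V at -0.20, ribosomal proteins at -0.14 and endothelial markers at -0.23. Camera placed hypoxia-induced genes lower with TMM though their mean stayed at 0.014, and they were at -0.015 with quantile normalization and -0.062 with a filter of 1 TPM, angiogenic genes at -0.0021 with that filter, and mitochondrial genome genes at -0.055 under 10% mitochondrial ribosomal RNA. In CLI against Control, immediate early genes were at -0.033 with the mitochondrial ribosomal RNA covariate, and macrophage markers, placed higher by camera despite a mean of -0.02, were placed lower at -0.41 with fry, -0.021 with TMM, -0.016 with quantile normalization, -0.031 with nuclear protein-coding scaling, -0.48 with that covariate, -0.29 with a filter of 1 TPM and -0.074 with TMM without CLI replicate 7. In IC-post against IC, hypoxia-induced genes were at 0.14 with fry, angiogenic genes at -0.044 under 10%, and camera placed fibro-adipogenic markers lower at 10% or more though their mean stayed at 0.24. In IC-post against Control, fry gave -0.37 for hypoxia-induced, -0.18 for angiogenic and -0.14 for slow-fibre genes. Camera there placed hypoxia-induced genes higher despite a mean of -0.02, and it placed them lower at -0.021 with TMM, -0.026 with quantile normalization, -0.023 with nuclear protein-coding scaling, -0.074 with a filter of 1 TPM and 0.012 under 10%, and angiogenic genes at -0.0010 with that filter.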

Other observations

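The filter of 1 TPM and the scores per pair were chosen after the results were seen. With that filter, 24 inflammatory cytokines and chemokines lay above other genes in CLI vs Control (mean 0.40 log2, 1 rose, 2 adjusted over the list alone; camera adjusted p = 0.00323, adjusted p = 0.471 with an estimated correlation) and in CLI vs IC (mean 0.32, 1 rose, 7 adjusted over the list alone; camera adjusted p = 0.0126, adjusted p = 0.536 with an estimated correlation). Markers of neutrophils and of lymphocytes were not called in CLI vs Control (camera adjusted p = 0.485 and 0.231), nor were skin keratinocyte markers (0.654), mast cell markers (0.0508) or Schwann cell markers (0.156). In CLI vs IC, mast cell and Schwann cell markers lay lower (means -0.41 and -0.26, camera adjusted p = 0.0253 and 0.0444; adjusted p = 0.375 and 0.536 with an estimated correlation). Tendon markers were lower in CLI vs Control (2 of 10 fell, 3 adjusted over the list alone; mean -0.70, camera adjusted p = 0.00114, adjusted p = 0.158 with an estimated correlation). Erythroid and platelet markers, which report blood in a biopsy, were lower in CLI vs IC (mean -1.15, 0 of 7 passed, 1 adjusted over the list alone; camera adjusted p = 3.18e-06, adjusted p = 0.0661 with an estimated correlation).

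Within pairs of IC and IC-post libraries, the mean of 12 immediate early genes with TMM was higher after revascularization in 10 of 10 pairs, by 1.13 ± 1.02 log2 (SD, n = 10; exact sign-flip p = 0.00195, the smallest that 10 pairs allow; adjusted over 32 lists 0.0625). The 13 mitochondrial genome genes were lower in 8 of 10 pairs (-0.41 ± 0.42, exact p = 0.0117, adjusted 0.188). The denervation list was higher in 8 of 10 (0.16 ± 0.22, exact p = 0.0410, adjusted 0.438). None of the 32 lists passed after adjustment, which 1 list alone could not do even at the smallest p that 10 pairs allow.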
